A study of Mus musculus with 5 samples.

How the data were processed

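The series holds 5 single-cell libraries from mice, made with a droplet-based 3' kit that tags each captured transcript with a molecular identifier (UMI). Per the labels, 1 library came from macrophages elicited with thioglycollate and 4 came from foreign body granulomas around sponge or silk, each at 2 and at 4 weeks. The authors deposited raw UMI counts for 21617 genes in 41191 cells, and the counts per cell summed to the totals that stand in the deposited table of cells. That table also gives the percent of mitochondrial UMIs of each cell, as deposited by the authors, together with the library of each cell and the authors' names for cell classes and subclusters. Cell Ranger 3.0.0, Seurat 3.0 and the mouse build mm10 are named, without their roles, per the submitters' processing notes. The filters applied to cells before deposit are not given in the sources used here. The lowest number of detected genes per cell was 201 and the highest mitochondrial share was 25.0% (24.98%).

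Cell classes were the authors' deposited classes: monocytes, macrophages and dendritic cells together (written Mo-Mac), fibroblasts, NK and T cells (NK/T), neutrophils, endothelial cells, B cells and myocytes. Each subcluster's 10 leading genes by fold, with 20 CPM added, were compared with marker lists for cell types. Among its 10 leading genes, myeloid subcluster C9 held 4 mast cell markers beside genes known from mature dendritic cells such as Ccl22 and Ccr7, so it may be a mixture. The neutrophil subcluster BP held 2 mast cell or basophil markers and the fibroblast subcluster KC 4 mesothelial markers. By the marker rule these 3 were left out of the compared classes together with the fibroblasts that the authors named low quality, and any dendritic cells in C9 went with it. C9 made up 1.63% of the deposited monocyte, macrophage and dendritic cell class in the control library and 4.27%, 4.74%, 2.42% and 5.52% in sponge at 2 weeks, sponge at 4 weeks, silk at 2 weeks and silk at 4 weeks. In the same order of granulomas, BP made up 0.287%, 0%, 1.09% and 6.76% of neutrophils, KC 0%, 0%, 3.38% and 1.09% of fibroblasts, and the low-quality cells 7.96%, 7.83%, 12.3% and 22.5% of fibroblasts.

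Raw counts were summed per library and class and expressed as CPM (counts scaled to a class sum of 1e6). A ratio between libraries is a log2 ratio with 0.5 counts added to each sum, and its 95% interval comes from the conditional binomial distribution of a pair of Poisson counts. Shares of cells carry exact (Clopper-Pearson) 95% intervals. Each group had 1 library, no test across libraries was run, no p-value was computed, and all such intervals cover counting error only. An additive model of material and time over the 4 granuloma libraries would leave 1 residual degree of freedom and was not run. A class entered a comparison with at least 50 cells in each library. For a gene at 0 counts the limit is set by 3 counts. Comparisons were granuloma against control, silk against sponge at matched times, and 4 weeks against 2 weeks within a material. The count of genes in a comparison is the number that differed at least 2-fold the same way in each of its contrasts, from genes with at least 100 UMIs and 50 CPM in the higher library, on the scale log2((CPM + 10)/(CPM + 10)). Where a class had few UMIs in 1 library, 100 UMIs asked for more CPM there, so that counts higher and lower were not on equal terms.

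Genes are named by a rule set before the data were examined, as were the gene lists, the markers, the comparisons and most other settings, the exceptions being named with their values. From the genes passing the same limits, without predicted gene models, ribosomal, mitochondrial, haemoglobin, immunoglobulin, T cell receptor and sex-linked genes, the rule takes the 12 highest and the 12 lowest of each comparison by the smallest change over its contrasts, all in 1 direction. It adds the 5 largest of opposite direction, up to 4 members of every list in each direction, and Il4, Il13, Ifng, Il17a, Il10, Dcstamp and Ocstamp.

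The 32 lists covered macrophage fusion, alternative activation, classical inflammatory activation, type I interferon response, interferon gamma response, MHC class II presentation, the lipid-associated programme, lysosome, complement, matrix remodelling, chemokines, tissue-resident macrophages, large peritoneal macrophages, growth factors, glycolysis and hypoxia, oxidative phosphorylation, cholesterol synthesis, lipid efflux, iron handling, oxidative stress, proliferation and dissociation stress in Mo-Mac cells. In NK/T cells they covered type 2, type 1 and type 17 lymphocytes, regulatory T cells, checkpoint genes and naive lymphocytes, in fibroblasts matrix, contractile and inflammatory genes, and in endothelial cells angiogenesis. A list's value is the median log2 ratio of members with at least 20 UMIs over both libraries, where at least 5 members remained, with an interval from 2000 bootstrap draws of the members. Its percentile among 10000 random lists of the same size, matched on mean expression in 20 bins, describes these libraries and is no test. Of 30 such medians with a member at 0 counts in 1 library, 4 moved by more than 0.005 when that member was set to its bound from 3 counts per library, and these are given beside the values. The few listed genes without a place in the count table were not analysed here. Some genes that the naming rule selects are not reported here.

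To compare shares of cells with a UMI across depths, each cell was thinned to a fixed number of UMIs, the 10th percentile of the shallowest library of its class, and shallower cells were left out. Doublets were scored with Scrublet in scanpy 1.11.5 at an expected rate of 6%. Its automatic threshold marked 100 control cells (1.11%), 87 cells of silk at 2 weeks (0.850%) and 6 of silk at 4 weeks (0.320%) but 0 in both sponge libraries, so it did not work there. Main values therefore keep all cells, and an alternative removed the cells with the highest scores, 0.8% per 1000 cells of a library, which took out 7.24%, 9.88%, 6.16%, 8.18% and 1.50% of cells (654 control, 1220, 474, 837 and 28 granuloma cells in the order above).

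Other alternatives were TMM scaling (edgeR 4.0.16), median-of-ratios scaling (DESeq2 1.42.0), the mean of per-cell CPM, offsets of 1 and 50 CPM, no count filter or 500 UMIs, list members with at least 100 UMIs, cells with at least 500 UMIs and at most 10% mitochondrial UMIs, thinned cells, at least 2 UMIs per cell, classes called from markers, a denominator of leukocytes, all cells of a library, and cells without another class's markers. The scalings moved the median of all genes by between -0.23 and 0.23 log2, and by more than 0.1 in 20 combinations of class, scaling and contrast. The largest moves were in NK/T cells of sponge at 2 weeks against control (0.23) and in neutrophils of silk against sponge at 4 weeks (-0.23). In Mo-Mac cells the largest was -0.12, for 4 against 2 weeks in sponge.

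The procedure was tested on simulated data drawn from the real means and library sizes with counting error only, so its shares say nothing about variation between libraries. For silk against sponge at 2 weeks (2965 genes), 98.5% of 67 genes simulated at 2.5-fold and 100% of 66 at 4-fold were counted as at least 2-fold, against 0% of 67 at 1.5-fold and 0% of unchanged genes. The 95% interval held the simulated ratio for 94.9% of genes. At 4 weeks (2934 genes) the shares were 94.0%, 100%, 0% and 0%, with 94.9% of ratios held. Lists of 15 genes shifted by 1 log2 unit lay beyond the 97.5th percentile in 100% of draws at both times, and unshifted lists in 0% at 2 weeks and 3% at 4 weeks. Gene positions are from GENCODE M21 on GRCm38 (mm10). Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3, were used.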

Results

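Cells of 5 libraries were profiled by droplet-based 3' RNA sequencing. The control library held macrophages that had been elicited with thioglycollate, a sterile irritant that draws macrophages into the peritoneal cavity. The other 4 libraries held cells of granulomas, the nodules of macrophages and connective tissue that form around material the body cannot remove, here around a sponge or around silk, taken at 2 or 4 weeks. The control library gave 9039 cells and 80521014 UMIs. Sponge gave 12347 cells and 96066597 UMIs at 2 weeks and 7701 cells and 50734356 UMIs at 4 weeks, and silk gave 10231 cells and 63570615 UMIs at 2 weeks and 1873 cells and 11207419 UMIs at 4 weeks. The median cell held 7109 UMIs in the control library and 5206, 3852, 4201 and 3818 in the granulomas. Here and below, values of the 4 granuloma libraries stand in the order sponge at 2 weeks, sponge at 4 weeks, silk at 2 weeks and silk at 4 weeks. Median mitochondrial shares were 3.66% in the control and 3.24%, 6.54%, 3.80% and 4.60% in the granulomas. Each group had 1 library without a replicate, no test across libraries was run, and every interval on a share or ratio covers counting error only. Gene positions are on GRCm38 (mm10) in the GENCODE M21 annotation.

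The makeup of the libraries by cell class shows which cells each granuloma yielded. Monocytes, macrophages and dendritic cells were the largest class in every library, at 87.5% of cells in the control (95% exact interval 86.8 to 88.2) and 60.2%, 62.8%, 73.6% and 59.1% in the granulomas. Fibroblasts, the cells that make collagen, were 4 of 9039 control cells and 18.7%, 21.1%, 9.25% and 14.7% of granuloma cells. Their share was lower in silk than in sponge at 2 weeks (-9.47 percentage points, interval -10.4 to -8.58) and at 4 weeks (-6.33, -8.16 to -4.41, or -11.5 with classes called from markers). Neutrophils were 0.133% of control cells and 8.48%, 4.29%, 8.04% and 3.95% of granuloma cells, so that they were less frequent at 4 than at 2 weeks in sponge (-4.20 points, -4.87 to -3.51) and in silk (-4.09, -5.09 to -2.98). NK and T cells were 4.06% of control cells and 3.74%, 3.99%, 2.62% and 8.17% of granuloma cells, a difference between times of 5.55 points in silk (4.30 to 6.92) and 0.245 in sponge (-0.307 to 0.811). B cells made up 8.23% of the control and 0.113%, 0.312%, 0.479% and 1.18% of the granulomas. Endothelial cells were absent among 9039 control cells, which allows a share of up to 0.033%, and made up 6.56%, 6.36%, 5.66% and 11.8% of the granulomas. The class deposited as myocytes was likewise unseen in the control and made up 2.21%, 1.22%, 0.332% and 1.12%. Its leading genes included Rgs5 and Notch3, which are known from pericytes, and 54.2%, 50%, 35.3% and 52.4% of its cells were called the same from markers. The class of monocytes, macrophages and dendritic cells was more frequent in silk than in sponge at 2 weeks (13.4 points, 12.2 to 14.7) and less frequent at 4 weeks (-3.72, -6.23 to -1.23), and that 4-week difference was 2.49 points the other way when classes were called from markers. Among leukocytes alone the differences were 3.87 and -6.35 points. Shares depend on how well each cell type came out of the tissue, which was not measured.

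**Figure D1:**
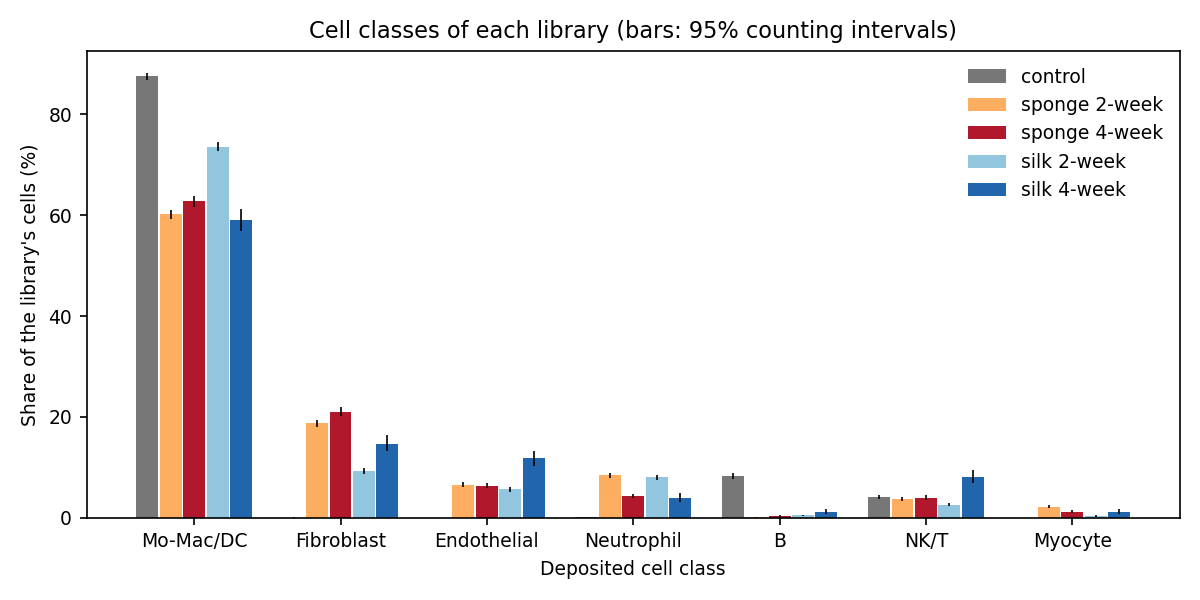
Share of each deposited cell class among the cells of each library, in percent, with exact 95% intervals as bars. Fibroblasts made up 18.7% and 21.1% of the sponge libraries and 9.25% and 14.7% of the silk libraries at 2 and 4 weeks.

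Granuloma macrophages were compared with the elicited control to ask how macrophages around a foreign body differ from macrophages recruited by an irritant. Inflammatory, chemokine and oxidative stress genes were far higher in the Mo-Mac cells of all 4 granulomas, and genes of peritoneal macrophages were lower. Il1b, the inflammatory cytokine interleukin-1 beta (chromosome 2, 129364570 to 129371139), stood at 3.11 CPM in the control and 1824, 581, 882 and 600 CPM in the granulomas, log2 ratios of 9.19 (9.01 to 9.39), 7.55 (7.36 to 7.74), 8.15 (7.96 to 8.34) and 7.59 (7.40 to 7.79). Cxcl2, a chemokine for neutrophils (chromosome 5, 90903871 to 90905938), stood at 38.7 CPM in the control and at 4043, 2108, 1887 and 2508 CPM, with the smallest log2 ratio 5.61 (5.55 to 5.66) in silk at 2 weeks. Ltc4s, the enzyme that makes leukotriene C4 (chromosome 11, 50236461 to 50238616), was lower, at 691 CPM in the control and 22.3, 28.2, 49.5 and 31.7 CPM. Cd5l, a secreted protein of tissue macrophages (chromosome 3, 87357881 to 87371073), stood at 265 CPM in the control and at 19.2 and 6.5 CPM in sponge and 3.9 and 0.47 CPM in silk. In this comparison 199 of 3157 genes were at least 2-fold higher in all 4 granulomas and 88 were at least 2-fold lower. With an offset of 50 CPM these counts were 110 and 42, and the count higher was 111 in thinned cells and 304 without a count filter.

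Among the other genes highest over the control, Clec4n and Clec4e, C-type lectin receptors for microbial sugars and lipids, reached 463, 522, 780 and 413 CPM and 533, 461, 522 and 314 CPM, against 2.8 and 9.4 in the control. Slc7a11, the cystine importer used for glutathione synthesis, reached 279, 287, 538 and 238 CPM against 1.6. Vegfa, the vascular growth factor, reached 283, 406, 522 and 313 CPM against 12.2. Plac8, a marker of monocytes, stood at 829, 282, 192 and 333 CPM against 6.4. The immediate early nuclear receptors Nr4a1 and Nr4a2 stood at 252, 394, 307 and 338 CPM and 279, 262, 231 and 229 CPM, against 7.8 and 4.3 in the control. Dusp5 and Csrnp1, which respond to growth factor signalling, lay between 144 and 255 CPM in the granulomas, against 2.0 and 4.6. On the lower side, Wfdc17 stood at 3654 CPM in the control and 1065, 231, 309 and 227 CPM in the granulomas. Fabp4, a fatty acid carrier, stood at 654 against 123, 38.7, 29.8 and 36.0 CPM, and Trf, the iron carrier transferrin, at 1126 against 150, 135, 115 and 180 CPM. Fcna, a lectin of the complement system, stood at 219 against 13.7, 5.5, 5.2 and 8.0 CPM. Padi4, a citrulline-forming enzyme, stood at 82.3 against 5.0, 1.8, 2.1 and 1.9 CPM, and Tecpr1 at 96.6 against 12.5, 15.4, 11.1 and 15.6 CPM.

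The lists for inflammatory cells lay above the control in each granuloma. The classical inflammatory list had medians of 4.90 (bootstrap 2.26 to 6.34), 2.74, 2.63 and 2.41 log2, with 17 of 18 measured members higher in sponge at 2 weeks. The chemokine list had 6.34, 4.83, 2.83 and 3.52, or 5.42 and 4.66 in the sponge libraries with Mo-Mac genes at 0 control counts set to their bound, and 22 of 24 members were higher in sponge at 2 weeks. Matrix remodelling genes, among them Mmp and Timp genes, had 3.30 (1.62 to 4.05), 2.59, 2.74 and 2.38, with 17 of 19 higher in sponge at 2 weeks. Growth factors had 3.74, 3.30, 2.76 and 3.48, and Inhba and Osm stood 7.95 and 4.60 log2 above the control in sponge at 2 weeks. Oxidative stress genes driven by NRF2 had 2.58 (1.71 to 3.05), 2.60, 2.80 and 2.15, with 12 of 13 higher in sponge at 2 weeks, Txnrd1 by 3.05. Glycolysis and hypoxia genes had 1.64 (1.16 to 2.68), 1.29, 1.52 and 1.01, and all 23 were higher in sponge at 2 weeks, the glucose transporter Slc2a1 by 3.07. Proliferation genes had 1.51, 1.36, 0.85 and 1.70, with 17, 17, 14 and 16 of 19 members higher. Dissociation stress and immediate early genes moved with all of these, with medians of 1.23 (0.72 to 2.65), 1.24, 0.88 and 1.36 and 17, 17, 16 and 17 of 20 members above the control. Among them were Ier3 (5.63), Egr1 (4.10) and Hspa1b (3.95) in sponge at 2 weeks, while Klf2 (-1.86) and Jun (-0.25) lay below the control.

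Genes of alternative activation by interleukin-4 and interleukin-13 had medians of 2.46 (1.22 to 4.22), 2.79, 2.73 and 2.75, with 14 of 18 members higher and 4 lower in sponge at 2 weeks. The higher members included Cish (7.02), Ccl17 (6.57), Socs1 (5.07) and Pdcd1lg2 (4.66). The lower ones were Retnla (-2.35), Mgl2, Clec10a and Irf4. In silk at 2 weeks Ccl17 (7.07), Cdh1 (6.15) and Socs2 (5.70) were higher and Retnla was lower (-4.65). Macrophage fusion and osteoclast-like genes had 0.57 (0.08 to 1.81), 1.03, 1.11 and 0.75, with 11, 12, 11 and 11 members higher and 4, 3, 3 and 3 lower. Dcstamp, a membrane protein needed for the fusion of macrophages into giant cells (chromosome 15, 39745930 to 39760938), stood at 0.646 CPM in the control and 16.3, 50.4, 50.5 and 59.0 CPM, a log2 ratio of 4.64 (4.23 to 5.11) in sponge at 2 weeks and 6.28 (5.88 to 6.73) in silk at 2 weeks. Its partner Ocstamp (chromosome 2, 165393760 to 165400405) stood at 0.054 and 6.45, 7.20, 13.6 and 8.83 CPM, log2 ratios of 6.74 (5.53 to 8.79) and 7.81 (6.62 to 9.86) for the 2-week sponge and silk libraries.

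A Dcstamp UMI was seen in 0.347% of control Mo-Mac cells and in 4.75%, 11.3%, 13.2% and 14.9% of granuloma Mo-Mac cells. With each cell thinned to 586 UMIs, which left out 130 control cells and 88, 205, 179 and 104 granuloma cells, the shares were 0.026% and 0.883%, 2.80%, 2.54% and 2.87%. Fibroblasts, which should lack this gene, had 0.705%, 1.34%, 2.01% and 0 of 211 cells (up to 1.42%) with a Dcstamp UMI. Their median depth was greater, at 15207, 12055, 13979 and 10133 UMIs against 4729, 3078, 4337 and 4217 in Mo-Mac cells. An Ocstamp UMI was seen in 0.051% of control and 1.63%, 1.95%, 3.33% and 3.16% of granuloma Mo-Mac cells, and in 0.564%, 0.468%, 0.251% and 0% of fibroblasts.

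Large peritoneal macrophage genes were lower than in the control, with medians of -3.52 (-4.29 to -1.0), -2.63, -2.80 and -2.63 and 11 of 13 members lower in sponge at 2 weeks, including the transcription factor Gata6 (-4.29), Naip1 (-4.89) and Tgfb2 (-4.71). Tissue-resident macrophage genes had -0.07, -0.98, -2.09 and -1.56, with 8, 12, 13 and 13 of 16 lower. Lysosome and cathepsin genes had -0.49, -0.49, -0.58 and -0.52, with 19, 20, 22 and 21 of 24 lower. Complement genes had 0.14, -0.58, -0.84 and -0.83, and iron-handling genes 0.23, -0.40, -0.46 and -0.39. The lipid-associated programme around Trem2 had -0.17, -0.74, -0.49 and -0.46, with members on both sides, Spp1 at 2.71 and Apoe at -1.73 in sponge at 2 weeks. Lipid efflux genes had -0.23, 0.27, 0.16 and 0.31, oxidative phosphorylation genes 0.15, 0.07, 0.12 and 0.24, and cholesterol synthesis genes -0.45, 0.32, -0.03 and 0.67. MHC class II genes had 0.50, 0.02, 0.19 and 1.16. The type I interferon list stood at 1.98 (1.52 to 3.61) with all 17 members higher in sponge at 2 weeks and at 0.58, -0.06 and -0.69 in the others, the last at 0.014 over all cells, and the interferon gamma list at 1.81, -0.15, -0.88 and -0.56, the last at -0.49 with a member at its bound.

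**Figure D2:**
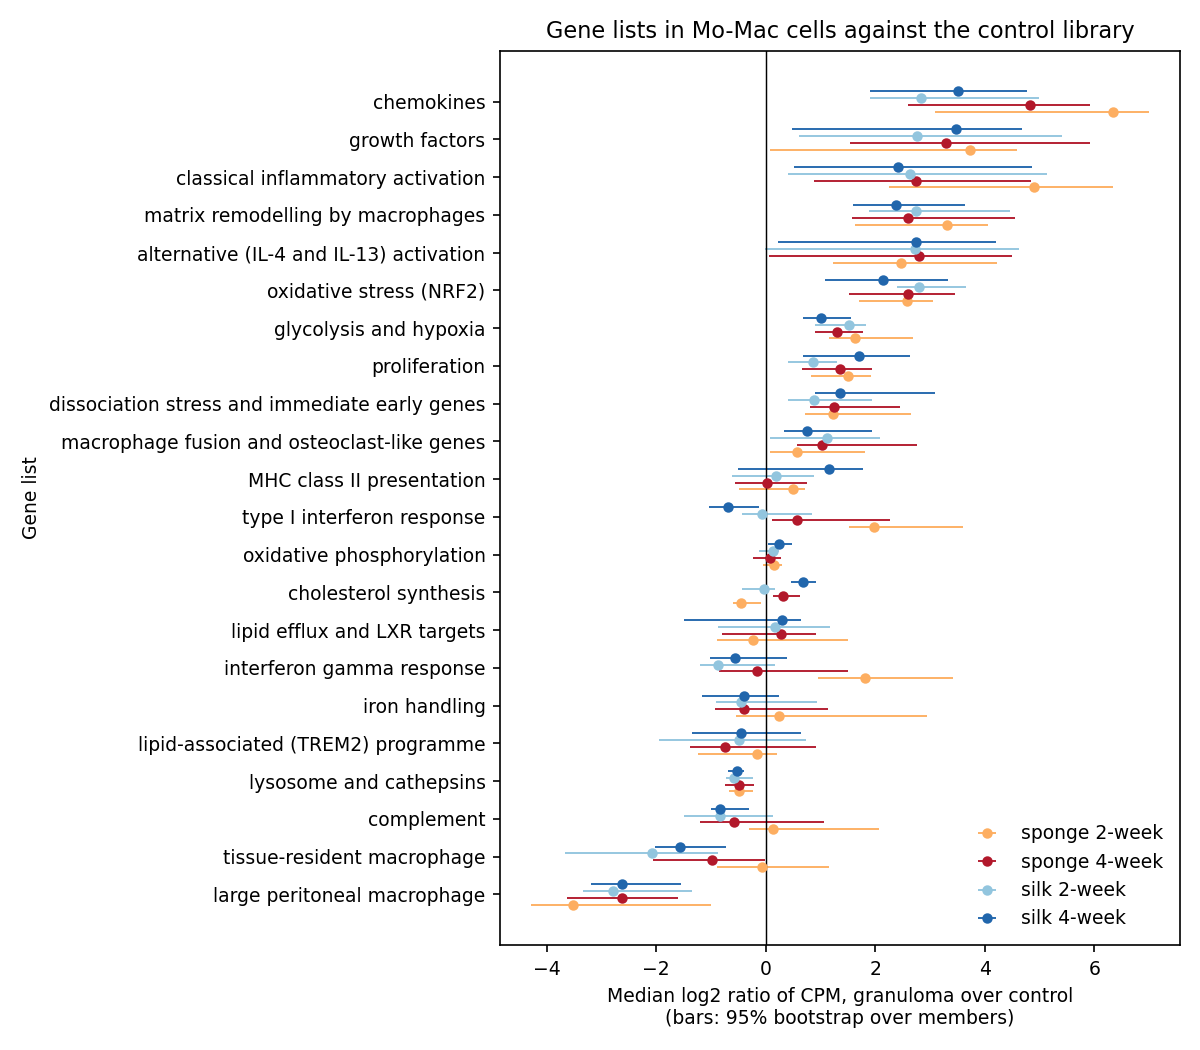
Median log2 ratio of CPM in Mo-Mac cells, each granuloma library over the control library, for 22 gene lists, with 95% bootstrap intervals over list members as bars. Chemokines (6.34, 4.83, 2.83 and 3.52) lay highest and large peritoneal macrophage genes (-3.52, -2.63, -2.80 and -2.63) lowest.

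Different subclusters made up the Mo-Mac cells compared: C1 was 81.9% of the deposited class, C9 included, in the control, C4 was the largest in sponge at 2 weeks (34.2%, with C6 at 19.8%, C5 at 18.3% and C7 at 15.1%), and C7 was the largest in sponge at 4 weeks (43.0%) and in silk (59.2% and 44.8%), with C6 at 33.3%, 28.6% and 28.5%. A cluster that comes mostly from 1 library may be that library, and the control differs from the granulomas in body site as well as in the foreign body. The dissociation stress list also lay above the control in all 4 granulomas. Any difference in how the cells were isolated was not tested and cannot be told apart from the foreign body in any comparison with the control. The 4 comparisons share the control: simulated unchanged groups, which carry counting error only and no variation between libraries, gave 0 genes in common in 100 draws, and independent lists of 299, 308, 296 and 275 higher and 191, 192, 198 and 171 lower genes would share 0.238 and 0.039, against the observed 199 and 88. With 1 control library that cannot be split, part of the excess may come from the shared control.

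NK and T cells of the granulomas were set against those of the control (367 cells against 462, 307, 268 and 153). The deposited NK/T class is not divided into subclusters, so that here and below its ratios may compare different mixtures of cells. Regulatory T cell genes were higher in every granuloma, with medians of 2.14 (1.68 to 2.93), 2.92, 3.46 and 3.26 and all 11, 10, 11 and 10 measured members higher. The sponge 4-week median was 2.07 in thinned cells and the silk 2-week median 2.16 over all cells. Ctla4, an inhibitory receptor of T cells, stood at 15 CPM in the control and 214, 392, 447 and 652 CPM. Genes of naive and central memory lymphocytes were lower, at -1.68 (-2.69 to -0.45), -1.09, -0.88 and -0.76, with 9, 7, 7 and 6 of 9 members lower. The list for type 17 and gamma-delta T cells had 0.93 (0.19 to 3.53), 3.22 (2.14 to 4.74), 1.11 and 2.52 (1.80 to 3.38). Checkpoint genes had 3.46, 3.03, 3.71 and 3.13, type 1 and cytotoxic genes 0.42, -0.06, -0.03 and 0.11, and the type 2 list 1.75, 2.13 and 2.25 in the libraries other than sponge at 2 weeks, where fewer than 5 members were measured. Among the highest single genes, Nr4a3 stood at 15.8 CPM in the control and 532, 821, 1043 and 1027 CPM, and Nr4a1 at 12.7 and 259, 587, 617 and 833 CPM. The heat shock gene Hspa1b stood at 10.3 and 295, 250, 310 and 491 CPM, and Odc1, the enzyme that starts polyamine synthesis, at 51.4 and 705, 1213, 1236 and 1372 CPM. The dissociation stress list over all cells of a library lay above the control as well, at 1.49, 1.70, 0.97 and 1.72. Several of the lowest genes of NK/T cells were macrophage genes, such as Apoe (4009 CPM in the control and 297, 247, 456 and 524 CPM), Gpnmb (395 and 13.9, 26.7, 13.8 and 27.7 CPM) and Trf. Without the cells of highest doublet score, Apoe in silk at 4 weeks (from -2.93 to 0.21), Trf in 3 libraries and Gda in 3 libraries turned direction. Lymphocyte genes on the lower side were Slfn1 (112 and 19.2, 13.3, 19.6 and 17.6 CPM) and Txnip (636 and 149, 109, 107 and 116 CPM). In all, 65 of 1462 genes were at least 2-fold higher and 40 at least 2-fold lower in each granuloma.

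Silk and sponge were compared at matched times to ask whether the material around which a granuloma formed went with a different macrophage state. Interferon-response genes and the chemokines Ccl2 and Ccl7 were lower in silk than in sponge, and genes such as Lyz1, Cx3cr1 and Itgax were higher. The type I interferon list had a median of -2.05 (-2.77 to -1.87) at 2 weeks and -1.5 (-1.64 to -0.73) at 4 weeks, with all 17 members lower at both times and the 0.00th percentile of random lists at 2 weeks. Isg15, a ubiquitin-like protein induced by interferon (chromosome 4, 156199424 to 156200818), stood at 21.7 against 195 CPM at 2 weeks (-3.16, -3.26 to -3.07) and 19.9 against 43.1 CPM at 4 weeks (-1.11, -1.40 to -0.85). Rsad2, the antiviral enzyme viperin (chromosome 12, 26442746 to 26456452), stood at 30.6 against 136 CPM and 13.6 against 42.0 CPM. Irf7, a transcription factor of the interferon response, differed by -3.02 (-3.11 to -2.93) and Ifi44 by -4.41 at 2 weeks, and Ifit2 by -3.10 at 2 weeks and -3.11 at 4 weeks. In the C7 cells alone, a setting chosen after the data were seen, the 2-week median was -1.42.

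The interferon gamma list was lower at 2 weeks, at -2.77 (-3.29 to -2.15) with 16 of 16 members lower, among them Cxcl9 (-4.87), Gbp2 (-3.43) and Iigp1 (-5.58), and stood at -0.22 (-1.13 to 0.07) at 4 weeks. The 2-week value was -1.55 in C7 cells alone and -1.84 over all cells, and the 4-week value was 0.086 with C9 included. Ccl7 and Ccl2, chemokines that draw monocytes, stood at 26.8 against 605 CPM (-4.50, -4.58 to -4.41) and 64.3 against 755 CPM (-3.55, -3.61 to -3.50) at 2 weeks, and 43.4 against 239 CPM (-2.46, -2.65 to -2.29) and 89.6 against 293 CPM (-1.71, -1.84 to -1.59) at 4 weeks. The chemokine list had -1.33 (-3.55 to 0.32) and -0.82 (-1.25 to -0.17), with Ccl8 (-6.79), Ccl12 (-6.20), Ccl5 (-6.16) and Ccl4 (-3.55) lower at 2 weeks and Cxcl3 (1.98) and Cxcl14 (1.92) higher. The inflammatory list had -1.48 (-2.27 to -1.07) with 16 of 18 members lower at 2 weeks and -0.01 at 4 weeks. Nos2, which makes nitric oxide, stood at 90.5 CPM in sponge at 2 weeks against 0.192 in sponge at 4 weeks, 0.609 in silk at 2 weeks and 0 counts in silk at 4 weeks and in the control. Ptgs2, which makes prostaglandins, stood at 562, 109, 113 and 72.4 CPM.

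Tissue-resident macrophage genes were lower in silk, at -1.71 (-3.14 to -1.28) with 15 of 15 members lower at 2 weeks and -0.45 with 8 of 14 lower at 4 weeks. Folr2, a folate receptor, stood at 27.1 against 239 CPM and 40.1 against 89.4 CPM, and Lyve1 (-3.57), Cd163 (-3.44) and Mrc1 (-1.71) were lower at 2 weeks. Subcluster C5, whose 10 leading genes included Ccl8, Mrc1, Folr2 and Ccl7, differed in share between the materials. It was 1.38% of the deposited class in silk against 18.3% in sponge at 2 weeks, and 3.2% against 9.06% at 4 weeks. The values of these genes and of the tissue-resident list therefore compare different mixtures of subclusters. Complement genes had -1.07 (-1.95 to -0.66) and -0.16, with C4b at -3.87 and Cfb at -2.64 at 2 weeks. Fcgr1, the high-affinity receptor for immunoglobulin G, stood at 35.3 against 269 CPM and 19.6 against 56.0 CPM, Oasl2 at 24.4 against 115 and 16.1 against 50.3 CPM, and Gas6, a ligand for clearance of dead cells, at 22.4 against 111 and 32.2 against 71.6 CPM. Ctsl stood at 1672 against 3407 and 858 against 1889 CPM, and Dab2 at 148 against 448 and 105 against 207 CPM. Collagen UMIs, which belong to fibroblasts, were also lower in silk Mo-Mac cells, with Col1a1 at 38.6 against 126 CPM and 17.3 against 155 CPM, which is 0.220% against 0.621% and 0.075% against 0.771% of the level in fibroblasts of the same library.

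Higher in silk were Lyz1, a lysozyme (chromosome 10, 117287797 to 117292868), at 549 against 125 CPM (2.13, 2.09 to 2.18) and 2603 against 840 CPM (1.63, 1.60 to 1.66). Cx3cr1, the fractalkine receptor, stood at 134 against 28.8 CPM (2.22, 2.13 to 2.31) and 207 against 89.3 CPM (1.21, 1.11 to 1.31). Itgax, which encodes CD11c, stood at 288 against 89.8 and 524 against 270 CPM. Mmp12, the macrophage elastase, stood at 2766 against 1004 and 4186 against 2639 CPM. Axl, a receptor for dying cells, stood at 118 against 35.4 and 196 against 111 CPM, and Itgal, which encodes CD11a, at 231 against 67.4 and 190 against 125 CPM. Pla2g7 (775 against 492 and 652 against 388 CPM) and Cybb, a subunit of the phagocyte oxidase (2109 against 1076 and 2156 against 1385 CPM), were also higher. At 2 weeks NRF2 targets had 0.64 (0.08 to 1.0), with Nqo1 (2.29), Gclm (1.46) and Srxn1 (1.26) higher, and at 4 weeks -0.09. Fusion genes had 0.28 and 0.10, with Dcstamp 1.63 (1.51 to 1.76) higher at 2 weeks and 0.23 (0.05 to 0.40) at 4 weeks and the protease Ctsk at 1071 against 349 CPM at 2 weeks. MHC class II genes had -0.39 at 2 weeks and 1.06 at 4 weeks, where Cd74 (1.24), H2-Eb1 (1.31) and H2-Ab1 (1.18) were higher, and the 2-week value was 0.68 in C7 cells alone and 0.10 over all cells. Of 2926 genes, 2 were at least 2-fold higher, 9 at least 2-fold lower and 6 at least 2-fold opposite at both times. Other settings gave from 1 (offset of 50 CPM) to 5 (mean of per-cell CPM) higher and from 4 (offset of 50 CPM) to 16 (no count filter) lower. Of the 9 lower genes, Col3a1, Sparc, Col1a2 and Col1a1 are fibroblast genes.

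The other Mo-Mac lists had these medians for silk against sponge at 2 and 4 weeks. Alternative activation had 0.04 and -0.07, with Arg1 at -1.76 at 4 weeks. Matrix remodelling had -0.26 and -0.40, with Fn1 (1.86) and Mmp19 (1.15) higher at 2 weeks, and growth factors -0.21 and 0.17, with Pdgfb (1.25) and Pdgfa (1.14) higher at 2 weeks. The lipid-associated programme had 0.08 and 0.07, lysosome genes -0.07 and -0.02, lipid efflux 0.38 and -0.12, cholesterol synthesis 0.30 at both times, iron handling -0.09 and -0.05, and oxidative phosphorylation -0.02 and 0.17. Glycolysis had 0.01 and -0.10 and large peritoneal macrophage genes -0.20 and 0.26. Proliferation had -0.65, with 17 of 19 members lower, and 0.23, the latter -0.13 in C7 cells alone and -0.76 over all cells. The dissociation stress list stood at -0.30 (-0.65 to -0.19) at 2 weeks, beside the lower inflammatory list, and 0.15 at 4 weeks, and the 2-week value was 0.08 in C7 cells alone. At 2 weeks the largest subcluster of the deposited class was C7 in silk (59.2%) and C4 in sponge (34.2%). The Mo-Mac values for silk against sponge therefore compare different mixtures of subclusters.

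**Figure D3:**
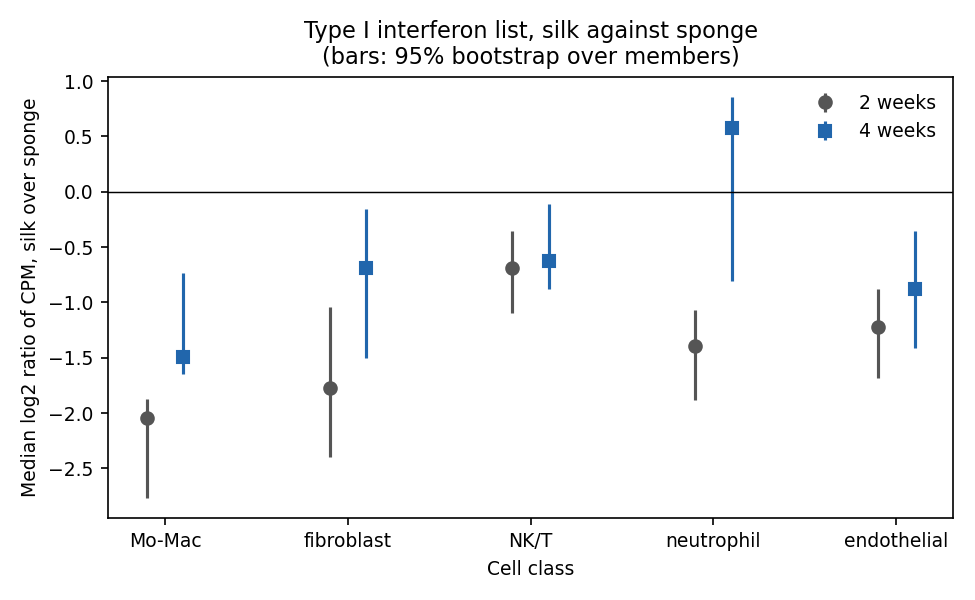
Median log2 ratio of CPM of the type I interferon list, silk over sponge, in 5 cell classes at 2 and 4 weeks, with 95% bootstrap intervals over list members as bars. At 2 weeks all 5 medians lay below 0, from -2.05 in Mo-Mac cells to -0.69 in NK/T cells.

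Fibroblasts of silk granulomas were higher than those of sponge in Stra6 and Tnfsf11 and lower in type I interferon genes. Stra6, the receptor for the retinol carrier, stood at 61.0 against 9.69 CPM at 2 weeks (2.65, 2.47 to 2.84) and 254 against 57.8 CPM at 4 weeks (2.14, 2.0 to 2.27). Tnfsf11, which encodes RANKL, the signal for osteoclast formation (chromosome 14, 78277445 to 78308043), stood at 59.0 against 15.5 CPM (1.93, 1.77 to 2.09) and 420 against 43.5 CPM (3.27, 3.15 to 3.40). Cryaa, a small heat shock protein known from the lens, stood at 60.4 against 11.8 and 428 against 109 CPM. Enpp2, which makes lysophosphatidic acid, stood at 184 against 52.4 and 393 against 127 CPM. F3, the tissue factor of coagulation, stood at 126 against 59.6 and 93.0 against 43.9 CPM, and Cdh11, a cadherin of mesenchymal cells, at 220 against 101 and 200 against 105 CPM. Lower in silk were Il1rl1, the interleukin-33 receptor (93.0 against 527 CPM, -2.50, -2.59 to -2.42, and 16.6 against 191 CPM, -3.51, -3.99 to -3.10). Also lower were Isg15 (19.5 against 155 and 26.5 against 75.6 CPM), Ifit1 (16.2 against 85.5 and 15.5 against 61.2 CPM), Ptx3 (118 against 394 and 97.9 against 161 CPM), Prg4, a lubricating proteoglycan (77.2 against 155 and 37.4 against 100 CPM), and Cxcl2 (320 against 589 and 59.3 against 232 CPM). The type I interferon list was lower in fibroblasts at 2 weeks (-1.77, -2.39 to -1.04) and 4 weeks (-0.69), and in neutrophils at 2 weeks (-1.39) but not at 4 weeks (0.58, -0.80 to 0.86). It was lower in endothelial cells at both times (-1.22 and -0.88) and in NK/T cells at both (-0.69 and -0.63).

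The collagen and matrix list stood at 0.04 and -0.03 in silk against sponge. Contractile myofibroblast genes were higher in silk at 2 weeks, at 0.60 (0.19 to 1.48) with 11 of 12 members higher, among them Acta2, smooth muscle actin (227 against 94.9 CPM, 1.26), and Des, desmin (119 against 3.68 CPM, 5.01). The list stood at -0.38 at 4 weeks, and over all cells of a library the 2-week value was -0.83. Inflammatory fibroblast genes had -0.48 at 2 weeks, with 11 of 15 lower but Cxcl5 (1.07) higher, and 0.11 at 4 weeks, where Saa3 was higher (1.53). Of 3018 genes, 4 were at least 2-fold higher, 3 lower and 8 opposite at both times. Among all deposited fibroblasts, the subclusters left out included, the largest subcluster was F1 in sponge (58.8% and 51.1%), F2 in silk at 2 weeks (48.3%) and F1 in silk at 4 weeks (45.7%), so that the values compare different mixtures.

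In NK/T cells, silk was higher than sponge in regulatory T cell genes at 2 weeks, at 0.99 (0.70 to 1.32) with 10 of 12 members higher, and stood at 0.28 at 4 weeks, and the 2-week value over all cells was -0.24. Il2ra, the interleukin-2 receptor, stood at 474 against 159 CPM at 2 weeks (1.58, 1.36 to 1.80) and 466 against 278 CPM at 4 weeks (0.74, 0.47 to 1.02). Ctla4 (447 against 214 and 652 against 392 CPM), Tnfrsf4 (263 against 155 and 335 against 197 CPM), Icos (719 against 352 and 1004 against 667 CPM) and Cd28 (342 against 200 and 503 against 321 CPM) were also higher at both times. Foxp3, the factor of regulatory T cells, stood at 97.9 against 29.3 CPM at 2 weeks. Gzmb, a killer cell protease, was lower in silk (426 against 876 CPM, -1.04, -1.21 to -0.88, and 194 against 382 CPM, -0.97, -1.35 to -0.62). So were Xcl1 (168 against 417 and 93.1 against 189 CPM) and Ifng, interferon gamma (54.1 against 101 and 37.8 against 110 CPM). Dusp1, of the dissociation stress list, was higher in silk at both times (745 against 378 and 1402 against 802 CPM). The type 2 list had 1.60 (0.79 to 2.49) with 7 of 7 members higher at 2 weeks, -0.02 over all cells, and 0.18 at 4 weeks. The naive list had 1.01 and 0.18, the type 1 list -0.43 and 0.06, the type 17 list 0.15 and -0.55 (0.25 over all cells at 4 weeks), and checkpoint genes -0.14 and 0.73. Of 1147 genes, 1 was at least 2-fold higher, 4 lower and 1 opposite at both times. The 1 higher was Lpl, a macrophage gene, and 3 of the 4 lower were the fibroblast genes Col3a1, Col1a1 and Col1a2, beside Plac8.

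Neutrophils of silk granulomas had more G0s2, an inhibitor of fat breakdown (3849 against 1545 CPM, 1.32, 1.26 to 1.38, at 2 weeks and 6263 against 3164 CPM, 0.99, 0.84 to 1.13, at 4 weeks), and Pim1 (2683 against 1391 and 4516 against 2723 CPM). They had less Hcar2 (803 against 1771 CPM, -1.14, and 614 against 2028 CPM, -1.71), Ccl4 (4671 against 9241 and 2975 against 11047 CPM), Cd274, the checkpoint ligand PD-L1 (275 against 572 and 132 against 409 CPM), and Il1f9 (760 against 1280 and 518 against 1005 CPM). At 4 weeks the silk library held 69 neutrophils, and the N1 subcluster was 72.7% and 79.7% of deposited silk but 34.8% and 69.4% of deposited sponge neutrophils. Endothelial cells of silk had more of several single genes known from lymphatic vessels, for which no list was run, with Ccl21a at 1980 against 266 CPM (2.90, 2.83 to 2.97) and 5159 against 2386 CPM (1.11, 1.06 to 1.16). Lyve1 stood at 459 against 75.1 and 912 against 404 CPM, Mmrn1 at 561 against 48.5 and 1141 against 644 CPM and Reln at 109 against 17.9 and 266 against 143 CPM. The deposited endothelial class is not divided into subclusters, so that here and below its ratios may compare different mixtures of cells, which was not tested. Glycam1, a ligand for lymphocyte homing, stood at 212 against 39.4 and 233 against 85.6 CPM, and Vwf at 368 against 196 and 514 against 263 CPM. Cxcl10, an interferon-induced chemokine, was lower (34.0 against 302 CPM, -3.15, and 26.2 against 99.9 CPM, -1.91), and Col3a1, a fibroblast gene, stood at 128 against 983 and 25.3 against 205 CPM. The angiogenesis list had 0.02 and 0.26, with Apln at -0.78 and -1.42. In endothelial cells 5 of 2823 genes were at least 2-fold higher and 13 lower at both times, and the lower ones included the fibroblast genes Col1a2, Col3a1, Col1a1 and Dcn and the neutrophil genes S100a8 and S100a9. In neutrophils the counts were 0 and 3 of 403, the 3 being Col1a1, Hcar2 and Cd274. These counts are not on equal terms, because a gene higher in silk needed 100 UMIs in silk at 4 weeks. Neutrophils there summed to 83031 UMIs, against 427914 in sponge at 4 weeks.

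Times were compared within each material to ask how a granuloma at 4 weeks differs from one at 2 weeks. In Mo-Mac cells, Lyz1, the phagocytosis gene Mfge8 and cholesterol synthesis genes were higher at 4 weeks, and Arg1, Vcan and Fpr2 were lower. Lyz1 stood at 840 against 125 CPM in sponge (2.75, 2.70 to 2.79) and 2603 against 549 CPM in silk (2.25, 2.22 to 2.27). Mfge8, which bridges macrophages to dying cells, stood at 294 against 116 CPM (1.35, 1.29 to 1.40) and 806 against 171 CPM (2.24, 2.19 to 2.29). Arg1, arginase (chromosome 10, 24915221 to 24927484), was lower at 172 against 569 CPM in sponge (-1.73, -1.78 to -1.68) and 50.6 against 324 CPM in silk (-2.67, -2.84 to -2.52). Vcan, a proteoglycan of monocytes (82.7 against 245 and 34.1 against 147 CPM), Fpr2, a formyl peptide receptor (12.7 against 91.1 and 25.1 against 73.1 CPM), and Cd274 (38.8 against 128 and 30.8 against 75.2 CPM) were lower as well. Cd38 (16.3 against 109 and 14.8 against 59.2 CPM), Hmox1, which breaks down haem (715 against 1489 and 407 against 1340 CPM), and Thbs1 (749 against 1610 and 480 against 980 CPM) were also lower. Higher were Itgax, Axl, Cd81 (97.8 against 50.6 and 156 against 61.1 CPM), Uchl1 (58.9 against 17 and 66.2 against 30.6 CPM), Fgfr1 (52.8 against 24.0 and 56.6 against 16.2 CPM) and Wfs1 (81.3 against 28.1 and 89.7 against 44.0 CPM). Gpnmb (878 against 496 and 1507 against 582 CPM), Atp6v0d2, a proton pump subunit (143 against 79.5 and 177 against 96.9 CPM), and Lpl, lipoprotein lipase (2699 against 1435 and 3512 against 2087 CPM), were higher at 4 weeks as well, though in sponge they stood at -0.25, -0.09 and -0.04 log2 within C7 cells alone. Of 2964 genes, 2 were at least 2-fold higher, 15 lower and 3 opposite in both materials, and the count lower was 6 within C7 cells alone and 9 with an offset of 50 CPM. The count higher was 4 with the mean of per-cell CPM and 6 with an offset of 1 CPM.

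Cholesterol synthesis genes stood at 0.64 (0.51 to 0.94) in sponge and 0.70 (0.45 to 0.84) in silk, with 17 and 18 of 18 members higher and at the 100th percentile of random lists in both. Among them were Sqle at 1.25 and 1.28, Cyp51 at 1.01 and Mvd at 1.19 in sponge, and Lss at 1.44 in silk. Glycolysis and hypoxia genes had -0.35 in both, with 17 of 23 and 18 of 22 members lower. In sponge the inflammatory list was lower (-1.45, 18 of 18 members), as were the type I interferon (-1.45, 17 of 17), interferon gamma (-2.08, 16 of 16), tissue-resident (-1.23, 13 of 15) and complement (-0.89, 12 of 13) lists. In silk these 5 lists stood at 0.18, -0.62, 0.32, 0.39 and -0.04. In C7 cells alone the tissue-resident value in silk was -0.12. In sponge C4 was 34.2% of the deposited class at 2 weeks and 1.47% at 4 weeks, and C7 15.1% and 43.0%. The sponge values of these lists, and of the single genes above, therefore compare different mixtures of subclusters. MHC class II genes had -0.45 in sponge and 0.93 in silk. Fusion genes had 0.55 and 0.14, alternative activation 0.24 and 0.11, chemokines -0.37 and 0.41, matrix remodelling -0.05 and -0.28, growth factors -0.08 and 0.06, and NRF2 targets 0.17 and -0.48. Proliferation genes had 0.03 and 1.06 (-0.41 over all cells in silk), lipid efflux -0.13 and -0.52, iron handling -0.28 and -0.21, the lipid-associated programme 0.32 and 0.17, lysosome genes -0.06 and 0.01, oxidative phosphorylation -0.07 and 0.15, and large peritoneal macrophage genes -0.36 and -0.43 (-0.29 with silk members at their bound). The dissociation stress list stood at -0.02 in sponge and 0.55 in silk, and the median mitochondrial share was higher at 4 weeks in both materials, at 6.54% against 3.24% and 4.60% against 3.80%.

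Among the genes at least 2-fold lower at 4 weeks in both materials and in each of the 5 classes were Lars2 (chromosome 9, 123366927 to 123462666), the lincRNA AY036118 (chromosome 17, 39847113 to 39848035), Gm10076 and Gm42418. In Mo-Mac cells AY036118 stood at 28.3 against 345 CPM in sponge (-3.61) and 7.1 against 247 CPM in silk (-5.10). Lars2, the mitochondrial leucyl-tRNA synthetase, stood at 78.5 against 365 CPM (-2.22) and 81.4 against 363 CPM (-2.16). No gene was higher in all 5 classes.

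**Figure D4:**
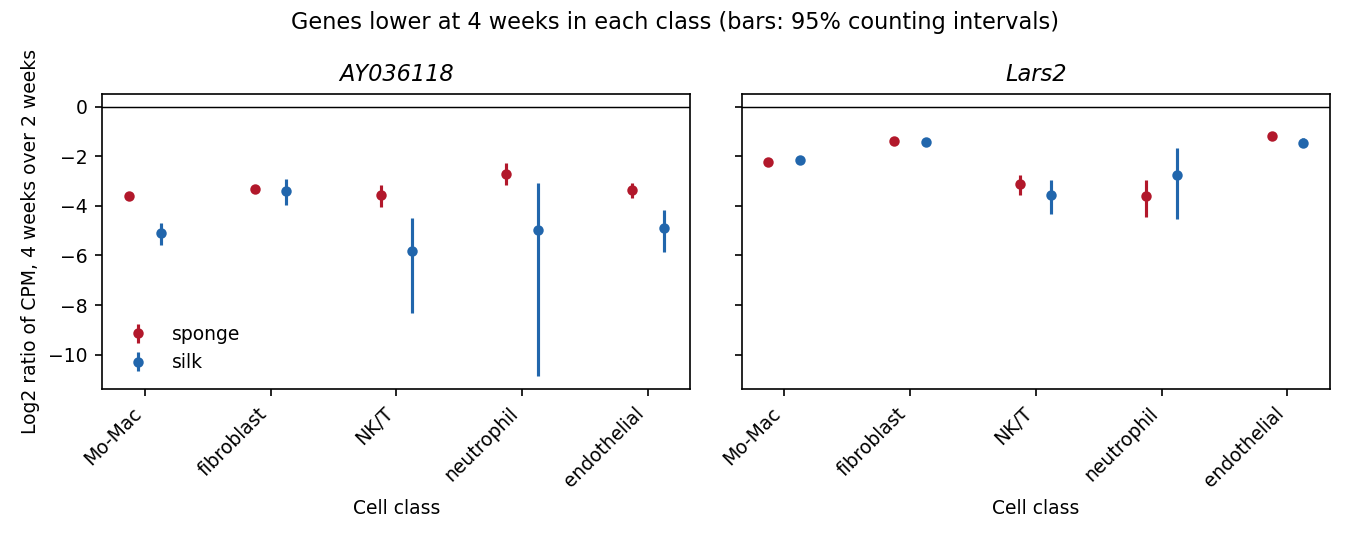
Log2 ratio of CPM at 4 over 2 weeks of AY036118 and Lars2 in 5 cell classes of sponge and silk granulomas, with 95% counting intervals as bars. Every point lay below 0, the nearest at -1.19 (Lars2, endothelial cells, sponge).

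Fibroblasts at 4 weeks were higher in Gsn, Pthlh and Klf2 and lower in contractile genes. Gsn, the actin-severing protein gelsolin, stood at 3474 against 1452 CPM in sponge (1.26, 1.24 to 1.27) and 5472 against 917 CPM in silk (2.58, 2.54 to 2.61). Pthlh, which encodes parathyroid hormone-related protein, stood at 61.6 against 18.1 CPM (1.77, 1.63 to 1.91) and 366 against 33.5 CPM (3.45, 3.28 to 3.62), and Klf2, a transcription factor of the dissociation stress list, at 704 against 257 and 969 against 365 CPM. Smoc2 (146 against 59.8 and 354 against 47.1 CPM), Col15a1, a basement membrane collagen (572 against 281 and 875 against 237 CPM), Tgm2 (258 against 83.0 and 519 against 151 CPM) and Igfbp5 (1038 against 553 and 907 against 458 CPM) were higher. Contractile genes had -0.46 (-0.58 to -0.05) in sponge, with 7 of 11 lower, and -1.65 (-2.39 to -1.25) in silk, with 11 of 11 lower, including Des (-3.07), Lrrc15 (-2.39), Cthrc1 (-1.72) and Acta2 (-1.53). The matrix list had 0.08 and 0.01, with Col12a1 (-2.49) and Tnc (-1.63) lower and Dcn (1.16) higher in silk. The inflammatory list had -0.16 and -0.14, with the complement gene C3 higher in silk (2.24) and Saa3 lower in sponge (-1.97). Fabp5 (58.9 against 159 and 50.6 against 281 CPM), Ptn (206 against 514 and 136 against 411 CPM) and C1qtnf3 (59.6 against 136 and 27.2 against 173 CPM) were lower. So were S100a9 (9.1 against 88.7 and 1.1 against 56.9 CPM) and Il1b (31.0 against 74.7 and 6.8 against 68.3 CPM), which are leukocyte genes. Of 3130 genes, 13 were at least 2-fold higher and 18 lower in both materials. Among all deposited fibroblasts, the subclusters left out included, F1 was 11.1% at 2 weeks and 45.7% at 4 weeks in silk. In sponge F1 was 58.8% and 51.1%. Gsn was among the 10 leading genes of F1, Col12a1 among those of F2 and Tnc among those of F3. The fibroblast values between times therefore compare different mixtures of subclusters, and ratios within a subcluster were not tested.

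Type 17 T cell genes were higher at 4 weeks in the NK/T cells of both materials. The list stood at 2.20 (0.60 to 3.15) in sponge, with 7 of 9 members higher, and 1.92 (0.16 to 2.26) in silk, with 6 of 9 higher. Il17a, the cytokine interleukin-17A (chromosome 1, 20730905 to 20734496), stood at 382 against 135 CPM in sponge (1.49, 1.26 to 1.73) and 415 against 86.4 CPM in silk (2.26, 1.86 to 2.68). Cd163l1 (3.15 and 2.05), Tcrg-C1, a constant region of the gamma-delta receptor (3.15 and 1.98), and Blk (3.13 and 2.49) were higher in both. Cxcr6, a chemokine receptor of tissue T cells, stood at 448 against 108 CPM (2.06, 1.81 to 2.31) and 367 against 146 CPM (1.33, 0.98 to 1.68). Gzmb stood at 382 against 876 CPM (-1.20, -1.36 to -1.03) and 194 against 426 CPM (-1.13, -1.51 to -0.78). Genes of the dissociation stress list were higher in the same cells, with Fosb at 909 against 378 and 1075 against 471 CPM, Dusp1 at 802 against 378 and 1402 against 745 CPM and Btg2 at 587 against 331 and 697 against 374 CPM, and over all cells of a library that list stood at 0.33 and 0.58. Regulatory T cell genes had 0.68 and -0.02, type 2 genes 0.93 (-0.29 over all cells) and 0.14, type 1 genes -0.88 and -0.22, checkpoint genes -0.94 and 0.55, and naive genes 0.38 and 0.20. Il1b and Hmox1, genes of macrophages, were also lower in NK/T cells at 4 weeks, and in silk their ratios were 1.48 and 0.14 without the cells of highest doublet score (Il1b 0.21 without Scrublet doublets). Of 1158 genes, 9 were at least 2-fold higher and 10 lower in both materials. Whether the type 17 and Gzmb values came from a different mix of cells in this undivided class was not tested.

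An Il17a UMI was seen in 2 of 367 control NK/T cells (0.545%, exact interval 0.066 to 1.96) and in 4.33% (2.66 to 6.61), 20.8% (16.4 to 25.8), 5.60% (3.17 to 9.06) and 11.1% (6.61 to 17.2) of granuloma NK/T cells. Thinned to 545 UMIs per cell, which left out 3 control cells and 3, 3, 4 and 16 granuloma cells, the shares were 0.275% and 2.18%, 10.5%, 1.52% and 5.11%, and with at least 2 UMIs required sponge had 2.38% and 15.3%. Mo-Mac cells, which should lack Il17a, had 0 of 7783 control cells and 0.014%, 0.109%, 0.014% and 0 of 1045 granuloma cells (up to 0.287%) with an Il17a UMI, at median depths of 7749 UMIs and 4729, 3078, 4337 and 4217, against 2725 UMIs and 3110, 2526, 2553 and 2369 in NK/T cells. Ifng was seen in 3.54% of control and 17.5% (14.2 to 21.3), 9.45% (6.42 to 13.3), 8.58% (5.52 to 12.6) and 5.88% (2.73 to 10.9) of granuloma NK/T cells, thinned to 0.824% and 6.32%, 3.29%, 3.41% and 2.19%, with at most 0.096% of Mo-Mac cells. Il10 was seen in 0.272% of control and 1.30%, 2.61%, 2.99% and 11.1% (6.61 to 17.2) of granuloma NK/T cells, thinned to 0% and 0.436%, 0.987%, 1.14% and 7.30%. Fibroblasts, at the greater depths given above, had 1.83%, 0.936%, 0.251% and 0 of 211 cells with an Il10 UMI. In sponge at 2 weeks fibroblasts thinned to 2165 UMIs had 0.285%, and neutrophils had 2.11%, or 0.389% thinned to 610 UMIs. With at least 2 UMIs required, the shares there were 0.649% of NK/T cells, 0.235% of fibroblasts and 0.287% of neutrophils. With only 6 NK/T cells holding a UMI, whether the NK/T share of sponge at 2 weeks lies above background is undecided. A UMI of Il10 was seen in 0.026%, 7.93%, 2.56%, 0.912% and 2.01% of Mo-Mac cells, which can make it. Il4, a cytokine of type 2 immunity, was seen in 3 of 367 control NK/T cells and in none of the granuloma NK/T cells, which allows shares of cells with a UMI, not of cells expressing the gene, of up to 0.649%, 0.977%, 1.12% and 1.96%. Il13 was seen in 0 of 367 control cells (up to 0.817%) and in 0 of 462 (up to 0.649%), 1 of 307, 2 of 268 and 0 of 153 (up to 1.96%) granuloma NK/T cells, too few to order the libraries, and these limits too are on cells with a UMI only.

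**Figure D5:**
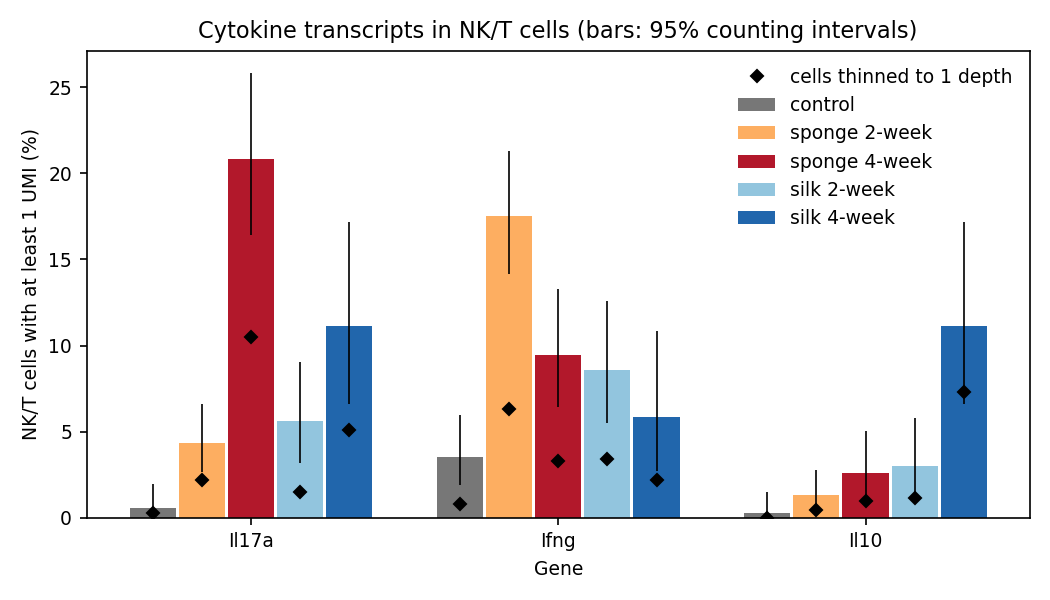
Share of NK/T cells with at least 1 UMI of Il17a, Ifng or Il10 in each library, in percent, with exact 95% intervals as bars and shares after thinning to 545 UMIs per cell as diamonds. Il17a was seen in 20.8% and 11.1% of NK/T cells of sponge and silk at 4 weeks, against 4.33% and 5.60% at 2 weeks.

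Neutrophils and endothelial cells at 4 weeks differed from those at 2 weeks as follows. In neutrophils, Jund, a subunit of the AP-1 transcription factor and a member of the dissociation stress list, was higher (2914 against 1235 CPM in sponge, 1.24, 1.14 to 1.34, and 3216 against 1429 CPM in silk, 1.17, 0.98 to 1.36), and 65 of 789 genes were at least 2-fold lower in both materials against 3 higher. The lowest included C1qb, Apoe, Pltp and Ctsc, which are macrophage genes. In endothelial cells, Igfbp5, a binding protein for insulin-like growth factors, stood at 426 against 42.9 CPM (3.31, 3.14 to 3.48) and 858 against 71.4 CPM (3.59, 3.40 to 3.78). Fgl2 stood at 662 against 64.0 CPM (3.37, 3.23 to 3.51) and 1110 against 437 CPM (1.35, 1.24 to 1.45). Cp, the copper carrier ceruloplasmin, stood at 203 against 13.1 and 348 against 99.2 CPM, and Fxyd6 at 286 against 11.6 and 352 against 117 CPM. Ccl21a and Reln were higher at 4 weeks as well, at 2386 against 266 and 5159 against 1980 CPM and 143 against 17.9 and 266 against 109 CPM. Whether these endothelial values came from a different mix of cells in the undivided class was not tested. The angiogenesis list had -0.06 and 0.33, and 20 of 2933 genes were at least 2-fold higher and 20 lower in both materials, the lower ones including Col3a1, Col1a1, Col1a2 and Il1b, genes of other cell types. The labels give no batch of library preparation, and any batch shared by the libraries of a time would not be separable from time.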

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

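The test of AY036118 and Lars2 in all 5 classes was written only after its result had been seen, it and the test by mitochondrial share were narrowed to these 2 genes afterwards, and the settings confined to C7 cells or without the highest doublet scores were added after the data had been seen.

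Genes of Mo-Mac cells whose log2 ratios at 4 against 2 weeks went opposite ways in sponge and in silk stood out, and for none of them was the difference between materials tested. Ccl8, a chemokine, stood at -3.94 in sponge and 1.99 in silk. Cxcl3 stood at 1.65 in sponge and -1.14 in silk, and the caveolae protein gene Cav1 at 1.20 and -1.05. Nfkbiz, a regulator of NF-kappaB, stood at -0.94 and 1.49, and at 0.25 (0.245) in sponge within C7 cells alone. The complement gene C1qb stood at -0.89 and 0.87. Subcluster C5, whose 10 leading genes included Ccl8, C1qa and C1qc, also moved in opposite directions. From 2 to 4 weeks it went from 18.3% to 9.06% of the deposited class in sponge and from 1.38% to 3.2% in silk. The Ccl8 and C1qb ratios therefore compare different mixtures of subclusters.

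AY036118 and Lars2 were lower at 4 weeks in every class and both materials, the ratio nearest 0 being -1.19 (-1.185). A difference in mitochondrial content is argued against, because among Mo-Mac cells with 3 to 5 percent mitochondrial UMIs the ratio nearest 0 was still -2.27 (-2.265). A difference in library preparation or sequencing between the 2-week and 4-week libraries was left undecided, because the genes were picked for being lower in all 5 classes and their shared direction gives it no support. The labels give no batch, so that explanation and a biological effect of time both stay open and untested.

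Collagen UMIs in leukocytes were lower in silk than in sponge, with Col1a1 in Mo-Mac cells at 0.621% and 0.771% of the fibroblast level in sponge and 0.220% and 0.075% in silk. Doublets of macrophages with fibroblasts are argued against as the main source, because only 4.97% (4.967%) of the collagen UMIs of sponge 2-week Mo-Mac cells lay in cells with 10 or more of them. Free RNA from fibroblasts may be the source, but the ratio of Col3a1 to Col1a1 left that undecided: over 10 pairs of library and class it differed from the fibroblast ratio by at most 1.54-fold (1.537), past the limit of 1.5 set beforehand. Of these pairs 1 passed 1.5-fold and 0 passed 2-fold, and the median fold was 1.15. A collagen UMI was seen in 5952 of 7113 Mo-Mac cells of sponge at 2 weeks. Fibroblasts were also the rarer class in silk at both times, and an effect of the material stays open and untested.

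Type I interferon genes were lower in silk than in sponge Mo-Mac cells at 2 weeks, with a median of -2.05. The makeup of the class by subcluster is argued against as the whole cause, since within C7 cells the median was -1.42 (-1.417, bootstrap -2.22 to -1.12, 4461 silk and 1122 sponge cells). Without the highest doublet scores the median was -2.01 (-2.011). That removal cannot decide on doublets, because it ranks cells by Scrublet scores, whose automatic threshold marked 0 cells in sponge at 2 weeks. Doublets therefore stay open. A change limited to macrophages is argued against by fibroblasts, at -1.77, for which free macrophage RNA is argued against because in sponge at 2 weeks the list stood at 0.759 of the Mo-Mac level, 15.5 times (15.519) the highest such ratio of a macrophage gene. The median nearest 0 over the other classes was -0.69 (-0.693, NK/T cells), but free RNA in NK/T cells, neutrophils and endothelial cells was not tested and stays open there. With 1 library per group, a difference between single libraries and an effect of the material both stay open and untested.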

How the results depend on the processing

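With 1 library per group no setting had replicates, and no test was run. No paired analysis was possible by replicate number, because each group holds replicate 1 only, and an additive model over the material and time pairs was not run. The smallest library, silk at 4 weeks, had 153 NK/T cells and 69 neutrophils, which limits every count in them, and free RNA and doublets limit genes of other cell types. Of the values under alternatives, 107 of 140 class shares, 29 of 38 share differences, 69 of 84 gene counts, 2596 of 2727 list medians, 3657 of 5341 named gene ratios and 50 of 80 shares of cells with a UMI stayed within the main value's interval or, for gene counts, within 1.5-fold of it. A turn of direction was counted for 1 share difference, 13 list medians and 27 named gene ratios. Only values whose main interval excluded 0 could be counted so, and other changes of sign were left out. Class shares, gene counts and shares of cells with a UMI have no direction to turn. The cause was not tested for any value below unless stated. The settings with C7 cells alone, with C9 and without the highest doublet scores were chosen after seeing the data.

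Within C7 cells alone, ratios at 4 against 2 weeks in sponge were -0.09 for Atp6v0d2, -0.25 for Gpnmb, -0.041 for Lpl and 0.24 for Nfkbiz, 6 genes were lower at 4 weeks, and cholesterol synthesis stood at 0.44. For silk against sponge at 2 weeks the same setting gave MHC class II 0.68, Mt3 -0.23, Tmem176a 0.23, dissociation stress 0.076, interferon gamma -1.55 and type I interferon -1.42, and at 4 weeks proliferation -0.13. The tissue-resident list in silk at 4 against 2 weeks was -0.12. With C9 included, interferon gamma for silk against sponge at 4 weeks was 0.086.

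Over all cells of a library, which by construction adds other cell types, silk against sponge at 2 weeks gave MHC class II 0.10, type 2 lymphocytes -0.018, interferon gamma -1.84, contractile genes -0.83, regulatory T cells -0.24 and type I interferon -1.77. At 4 weeks it gave type 17 0.25 and proliferation -0.76. Between times it gave type 2 lymphocytes -0.29 in sponge and proliferation -0.41 in silk. Against control it gave regulatory T cells 2.16 in silk at 2 weeks and type I interferon 0.014 in silk at 4 weeks.

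The share of NK/T cells with Il17a was 2.38% and 15.3% in sponge at 2 and 4 weeks with at least 2 UMIs required. Thinning, which by construction lowers shares, gave 2.18% and 10.5% in sponge and 1.52% and 5.11% in silk. With classes called from markers, silk minus sponge was -11.1 and -11.5 points for fibroblasts at 2 and 4 weeks and 10.1 and 2.49 points for monocytes, macrophages and dendritic cells, the last reversed. Among leukocytes alone these last were 3.87 and -6.35 points, NK/T cells in silk at 4 minus 2 weeks 8.20 and neutrophils in sponge -5.69. Without cells over 10% mitochondrial or under 500 UMIs the neutrophil value was -3.33.

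With the mean of per-cell CPM, Apoe in NK/T cells for silk against sponge at 2 weeks was -0.20, Mo-Mac genes at least 2-fold higher numbered 4 between times and 5 between materials, and type I interferon for silk against sponge at 2 weeks was -1.86. Without a count filter, which admits more genes, 304 Mo-Mac genes were higher than control, 5 higher at 4 weeks and 16 lower in silk. An offset of 1 CPM gave 6 higher at 4 weeks. An offset of 50 CPM, which shrinks ratios, gave 110 higher and 42 lower than control, 1 higher and 4 lower in silk, and 9 lower at 4 weeks. Without cells holding other class markers, 5 Mo-Mac genes were higher in silk and type I interferon at 4 weeks was -1.76.

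Thinned to 1 UMI number, NK/T cells gave for silk against sponge Apoe -0.35 at 2 weeks and Bst2 0.19, Kcnq1ot1 -0.21, Rab11b 0.11 and Stmn1 0.012 at 4 weeks, Hspa1a 0.30 at 4 against 2 weeks in sponge, and regulatory T cells 2.07 in sponge at 4 weeks against control. Mo-Mac genes then numbered 111 higher than control and 4 higher in silk. Without Scrublet doublets, Il1b in NK/T cells of silk at 4 against 2 weeks was 0.21. Without the highest doublet scores it was 1.48, with Hmox1 0.14, Il1rn 0.67 and Mmp19 0.97. That setting gave, for NK/T cells against control, Apoe 0.21 in silk at 4 weeks, Gda 0.25 in sponge at 2 weeks and 0.37 and 1.10 in silk, and Trf 0.27 in sponge at 4 weeks and 0.58 and 0.41 in silk. For silk against sponge at 4 weeks it gave endothelial Ccl2 0.025 and neutrophil Fn1 0.064.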

Other observations

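Some Mo-Mac genes differed between silk and sponge in opposite directions at 2 and 4 weeks. Retnla, a secreted protein of alternatively activated macrophages, stood at 674 CPM in the control and 132, 191, 26.9 and 547 CPM in the granulomas, a log2 ratio of silk to sponge of -2.30 (-2.39 to -2.21) at 2 weeks and 1.52 (1.45 to 1.58) at 4 weeks, and within silk it was 4.35 (4.25 to 4.45) higher at 4 weeks. Tmem176a and Tmem176b, paired membrane channel genes of antigen-presenting cells, stood at -1.61 (-1.615) and -1.70 at 2 weeks and 1.39 and 1.24 at 4 weeks. Within C7 cells Tmem176a was 0.23 at 2 weeks. Mt3, a metallothionein, stood at 1.37 and -1.17, and at -0.23 within C7 cells at 2 weeks, and the platelet chemokine gene Ppbp at 1.29 and -1.19.

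In fibroblasts the same crossing was seen for Timp3, an inhibitor of matrix proteases (161, 285, 579 and 96.0 CPM in the granulomas), Tnn, the matrix protein tenascin-N (87.5, 60.4, 332 and 15.9 CPM), Mmp3, a matrix protease (528, 763, 205 and 1686 CPM), and Spp1, osteopontin (644, 811, 1329 and 271 CPM). In subcluster C9, whose leading genes held mast cell markers beside dendritic cell genes, so that its cells are of mixed or unsettled type, Il4 was seen in 4 of 129 control cells (3.10%) and in none of the granuloma cells, which allows shares of cells with a UMI, not of cells expressing the gene, of up to 0.946%, 1.31%, 1.65% and 4.92%.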
